A study of Mus musculus with 2 samples.

How the data were processed

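CUT&RUN was performed on cultured mouse splenic NK cells, with 1 library made with an antibody against Aiolos and 1 library made without a primary antibody. The peak list deposited for the series was the starting point, and reads and coverage tracks were not analysed here. Per the submitters' processing notes, which give no role or order, the tools were MACS2, Bowtie2, Picard and SAMtools and the genome build was mm10. The q cutoff, the duplicate filter and the use of the library without antibody as control are not given in the sources used here. The library kit and culture are per the labels' protocols. Peaks come from 1 library, so they are neither pooled nor compared between replicates.

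Per the file headers, the authors gave each peak a signal value, which is taken here as MACS2's fold enrichment, the ratio of the pileup plus 1 to the local background plus 1 at the summit. Per the file headers, the authors also gave the -log10 of the p-value and of the q-value of each peak. The score deposited by the authors is 10 times the -log10 q without its decimals. The deposited columns further hold the peak position, width and summit, an annotated transcript, a gene and a distance from the peak edge to the transcription start. These values are the authors' own comparison and served to describe, rank and filter peaks within this list. Coordinates are 1-based and on mm10.

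The depth of the libraries was recovered from the peak values. With the fold in that form and the p-value of MACS2 as the Poisson probability of exceeding the pileup, a whole pileup and a background were solved for each peak. All 1404 peaks were solved with an error in -log10 p of at most 1.75e-05. The background had a floor of 0.186 tags at 365 peaks. Within a tolerance of 0.0002, another 386 peaks lay on whole multiples of 0.586 tags and the remaining 653 on whole multiples of 0.0121 tags, the value of 1 tag spread over a window of 10000 bp, with 0 peaks on neither. About 3.3% of values would meet the smaller step by chance. Tags spread over a shorter window whose step is a multiple of this one would meet it too, so the window length was not resolved. Such steps arise when a control library of 1.71 tags per antibody tag is scaled to the antibody library, and fragments of 207 bp, the shortest peak width, are assumed. The floor corresponds to 898 antibody tags per Mb of mappable genome. If the mappable genome was set to 1.87 Gb, the preset for mouse, which is an assumption, the library with antibody held about 1680000 tags and the control about 2870000. Each fold has a 95% interval from the exact Poisson interval of its pileup with the background treated as fixed, so it covers counting error only, and duplicates of 1 molecule would make it too narrow.

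A gene had a peak when the authors' annotation named it. All 1404 gene identifiers matched the gene table (GRCm38.p6, the same assembly as mm10), 10 peaks carried another symbol, and 1399 of 1400 annotated transcripts on assembled chromosomes overlapped the same gene there, with 4 peaks on unplaced sequences. A promoter peak had its centre within 1000 bp of the start of its annotated transcript. The authors' own distance runs from the peak edge and gives 919 such peaks. This choice between centre and edge was made with both counts known, and the edge serves as an alternative. The limit of 10000 bp from the start used below is measured from the peak edge. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes of the table, 21900 genes in all, with Benjamini-Hochberg adjustment over 23 lists and a threshold of 0.05. The lists overlap: the bZIP list contains the AP-1 core list, and Nfil3 is in both the bZIP and the NK transcription factor list. Zfp683 was not in the protein-coding table. The background includes genes that are silent in NK cells, since no expression values were used. Medians were compared with two-sided permutation tests of 100000 resamples. Shares have exact Clopper-Pearson intervals at 95%.

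The lists, tests and rule for named genes were fixed before the data were examined, except where stated. The random placement against gene ends and the comparison of upstream with downstream summits were not among the fixed tests. The rule names every Ikaros family and AP-1 core gene with a peak, the 15 protein-coding genes with the highest fold at a promoter peak, and up to 4 genes per other list with the highest fold. Some genes that the rule names are not reported here, without replacement. Il10 and the genes of the closing observations were named after their values were seen. The alternatives fixed then were the 727 peaks at or above the median -log10 q, peaks above the median fold, merging within 500 bp, leaving out mitochondrial, Y and unplaced sequences, promoter windows of 500 and 3000 bp, the authors' annotation class, any overlap with the window, peaks within 10000 bp of the start, promoter peaks alone, 10000 random lists matched on gene length in 10 groups, all genes as background, the wider bZIP list, and the strongest peak per gene. Alternatives added after seeing the data were random lists matched on assignment territory, a background without olfactory receptor, vomeronasal receptor and Gm genes, and pileup in place of fold. Assignment territory was gene length plus the nearer part of each gap to the neighbouring protein-coding genes. Other genes were left out of it, though 98 genes with a peak were not protein-coding. A test of 14 sequence motifs at peak centres was planned and not run, because it needs a genome sequence, which was not used here.

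The methods were tested on simulated data. Pileups were recovered exactly for 100% of 1388 simulated peaks. Among 1150 simulated null lists over 21900 genes, 1 was called, and a list with planted peaks was called in 50 of 50 simulations. Random lists matched on assignment territory called 0 of 230 null lists and the planted list in 10 of 10. In these list simulations the peaks fell on genes independently, so lists of neighbouring genes were not covered. The planted list was the immediate-early list with a peak added at 9 of its 28 genes, so smaller lists and weaker enrichments were not covered. The permutation test of medians called 5 of 100 null differences and 100 of 100 shifted ones. It was run on 260 normal values with a shift of a full standard deviation. Its power for smaller shifts, or for a group as small as the 7 AP-1 core peaks, was not tested. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.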

Results

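Aiolos, the zinc finger transcription factor encoded by Ikzf3 and a member of the Ikaros family, was mapped on chromatin in mouse natural killer (NK) cells by CUT&RUN. In this assay an antibody tethers a fusion of protein A and micrococcal nuclease to the protein of interest, and the DNA cut around it is sequenced. The NK cells came from spleen and were expanded in culture with 50 ng/ml interleukin-15 to at least 500000 cells per sample. There were 2 libraries, 1 made with the Aiolos antibody and 1 made without a primary antibody. The authors called 1 set of 1404 peaks on the mm10 build, and each fold enrichment, q and gene assignment given here is their own value. With 1 library per group there is no replicate error, and every interval covers counting error only. The summit of a peak held 4 to 63 tags with a median of 8, as recovered from the authors' values, and 999 peaks (71.2%) rested on 10 tags or fewer.

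The first comparison asks where in the genome the antibody library exceeded its background. Most Aiolos peaks lay at gene starts: 910 of 1404 had their centre within 1000 bp of the annotated transcription start, a share of 64.8% (95% exact Clopper-Pearson interval 62.3 to 67.3). Outside promoters, the authors' annotation placed 194 peaks in distal intergenic sequence, 190 in introns, 32 in exons, 12 in 3' untranslated regions and 2 in 5' untranslated regions. The peaks named 1276 genes, of which 1178 were protein-coding, 5.38% of the 21900 protein-coding genes of the gene table, and 1173 genes had a single peak. Without strand in the gene table, chance was gauged by nearness to either end of a gene. Of peak centres, 62.5% lay within 1000 bp of a gene end, against a mean of 6.67% and a highest value of 8.93% over 100 random placements on the same chromosomes. These ends are not the transcript starts used above, so the random share is no bound for the 64.8%. Peak widths ran from 207 to 1517 bp with a median of 265.5 bp, and fold enrichments from 3.63 to 25.3 with a median of 6.44. The promoter share was 59.2% with a window of 500 bp and 71.6% with a window of 3000 bp.

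Within promoters, the summits did not centre on the start. They formed a cluster 101 to 250 bp upstream, with 234 summits, and another 50 to 149 bp downstream, with 208 summits, while the 100 bp just upstream of the start held 69. Of these 511 summits, 13.5% (95% exact interval 10.7 to 16.8) lay in that gap, where equal density over the windows gives 28.6%. The median summit position over all 910 promoter peaks was -79.5 bp, with quartiles at -238 and 96 bp. Upstream summits numbered 509 and downstream summits 401 (two-sided exact binomial p = 0.000384). The 3 windows were set after the distribution had been seen.

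**Figure D1:**
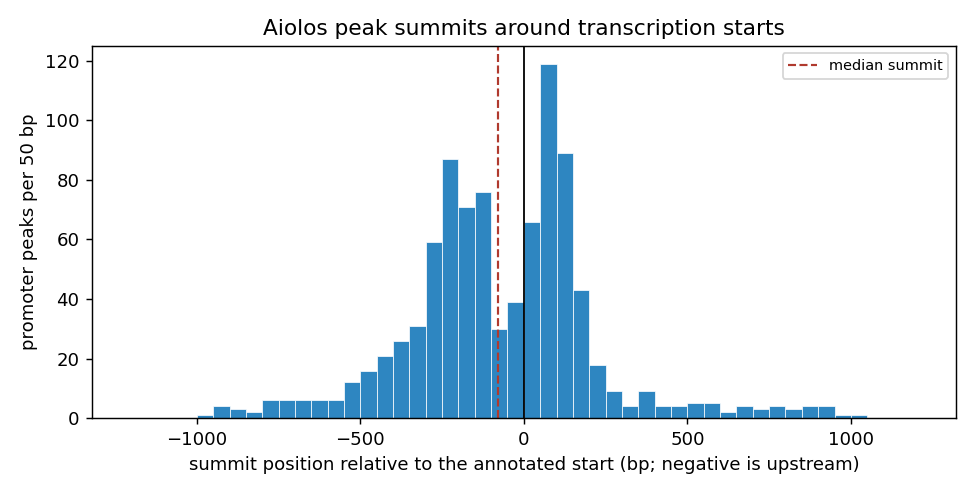
Summits of the 910 promoter peaks by position relative to the annotated transcription start in bp (x axis, negative is upstream) and number of peaks per 50 bp (y axis). The solid line marks the start and the dashed line the median at -79.5 bp, which falls between a cluster upstream and a cluster downstream.

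The second comparison asks whether promoter peaks were stronger than the others. Promoter peaks had a median fold enrichment of 6.60 (quartiles 5.53 and 8.27) and the 494 other peaks 5.90 (quartiles 5.06 and 7.59). The difference in median was 0.16 on the log2 scale (two-sided permutation test with 100000 resamples, p = 0.00014), and 41 of the 50 strongest peaks were promoter peaks. Peaks within 1 list are features and not replicates, so the test describes this library. In the 727 peaks with the highest -log10 q the difference was 0.085 (permutation p = 0.147), among peaks above the median fold 0.091 (permutation p = 0.0195), and with pileup in place of fold 0.36.

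The strongest promoter peak belonged to Cdca3, a cell division gene, on chromosome 6 at 124829147 to 124830073, overlapping the start, with a fold enrichment of 23.3 (95% exact Poisson counting interval 15.8 to 33.4, from 28 tags). Hnrnpl, which encodes a splicing factor, had 3 promoter peaks, the strongest at 21.7-fold (14.5 to 31.5) on chromosome 7 at 28810306 to 28810661. Next came Coro1c, a coronin that binds actin, at 17.8-fold (11.5 to 26.6), and Fntb, the beta subunit of protein farnesyltransferase, at 17.7-fold (11.1 to 26.9). Ap1m1 and Bloc1s3 each had a promoter peak of 16.9-fold, Erh of 15.8-fold, Slc35f5 of 15.3-fold and Atf7, a bZIP transcription factor, of 15.2-fold. Cryzl1, Mtmr4 and Serpini1 each reached 14.5-fold, and Coa7 and Fbxo5, an inhibitor of the anaphase-promoting complex, each reached 14.3-fold. The counting intervals of Coro1c and Fbxo5 (8.56 to 22.8) overlapped, so the order among these genes was not resolved at this depth.

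The series title names AP-1, and the third comparison asks whether genes for the AP-1 subunits carried Aiolos peaks. Of the 12 core AP-1 genes, Fos, Fosb, Jun and Junb had a peak, and Jund, Fosl1, Fosl2, Batf, Batf2, Batf3, Jdp2 and Atf3 had none. The share was 33.3% (95% exact interval 9.92 to 65.1) against 5.36% of other protein-coding genes, an odds ratio of 8.82 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0112 over 23 gene lists). Fosb stood out among them with 4 assigned peaks. Its promoter peak on chromosome 7 at 19310073 to 19310311, 22 bp upstream of the start, had a fold enrichment of 13.5 (8.38 to 20.7, 19 tags). Another, at 19300553 to 19300986, lay 8.61 kb downstream of the start in an exon of another transcript and had 11.7-fold (6.63 to 19.5). The remaining 2 were a peak of 5.86-fold in a 3' untranslated region and an intergenic peak of 4.72-fold, 9.80 kb upstream of the start.

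The other AP-1 core genes each had 1 peak. The peak assigned to Fos, on chromosome 12 at 85447250 to 85447475, lay 26.4 kb upstream in intergenic sequence with 7.33-fold enrichment (3.75 to 13.3). The peak assigned to Jun, on chromosome 4 at 95166530 to 95166979, lay 114 kb upstream in an intron of another transcript with 5.06-fold (2.21 to 10.7, 5 tags). Junb had a promoter peak on chromosome 8 at 84978719 to 84978931, 1 bp upstream of the start, with 3.98-fold (1.74 to 8.39, 5 tags) and a -log10 q of 1.31. The wider list of 30 bZIP genes, which contains the core, had 10 genes with a peak (odds ratio 8.86, Fisher's exact test, adjusted p = 5.02e-05), among them Atf7, Atf4 with a promoter peak of 8.85-fold and Bach2, a bZIP repressor of lymphocytes, with an intronic peak of 7.37-fold.

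With only promoter peaks, 2 AP-1 core genes were left, Fosb and Junb (odds ratio 5.09, Fisher's exact test, adjusted p = 0.241), and the call also ended within 10000 bp of the start (4.18, adjusted p = 0.239), in the 727 peaks with the highest -log10 q (6.75, adjusted p = 0.174) and among peaks above the median fold (7.16, adjusted p = 0.188). In strength, the 7 AP-1 core peaks had a median fold enrichment of 5.86 against 6.44 for the 1397 others, a difference of -0.14 on the log2 scale (two-sided permutation test, p = 0.483). The direction turned to 0.54 among the 727 peaks with the highest -log10 q (permutation p = 0.0249) and among peaks above the median fold (permutation p = 0.0281). Each of these sets held 3 AP-1 core peaks, 2 assigned to Fosb and 1 to Fos, so the peaks are not independent. With pileup in place of fold the difference was 0.17 (permutation p = 0.75). With the strongest peak per gene it was -0.11 (permutation p = 0.649).

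**Figure D2:**
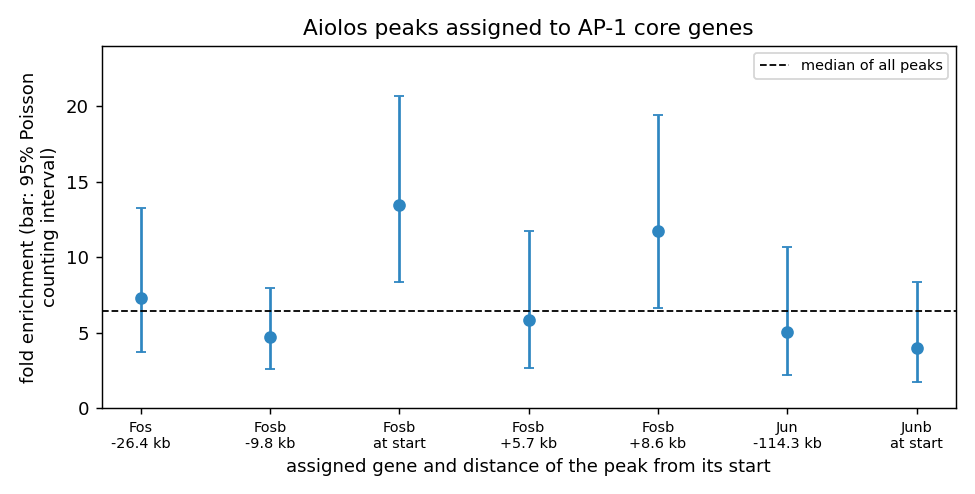
Fold enrichment (y axis) of the 7 peaks assigned to AP-1 core genes, ordered by gene and by distance from the gene start in kb (x axis). Points are the authors' fold enrichments, bars the 95% Poisson counting intervals and the dashed line the median of all peaks at 6.44; the Fosb promoter peak reaches 13.5 and the Junb promoter peak 3.98.

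The fourth comparison took 23 gene lists, of which 6 carried peaks more often than other protein-coding genes at an adjusted p below 0.05, with 10 lists at an unadjusted p below 0.05. A lower frequency could not have passed the test, since 0 genes with a peak in the largest list size, 39 genes, gives an unadjusted Fisher's exact p of 0.271. NK cell transcription factors had 9 of 28 genes with a peak (32.1%, odds ratio 8.39, Fisher's exact test, adjusted p = 7.64e-05). Rora had a peak of 9.66-fold (5.22 to 16.6) in an intron of its own, 161 kb upstream of the start of the transcript assigned to it, Runx3, a Runt family factor of cytotoxic lymphocytes, a promoter peak of 7.24-fold (3.58 to 13.5), Irf2 a promoter peak of 7.57-fold and Cxxc5 a peak of 7.57-fold 10.6 kb downstream of its start. Immediate-early and NF-kB feedback genes also had 9 of 28 (odds ratio 8.39, adjusted exact p = 7.64e-05). Egr1, a zinc finger gene induced within minutes of stimulation, had a promoter peak of 14.1-fold (8.90 to 21.5) on chromosome 18 at 34860501 to 34861109. Zfp36, which promotes mRNA decay, had its strongest peak at 10.3-fold, Zfp36l1 at 8.72-fold and Dusp1, a phosphatase of MAP kinases, at 8.20-fold.

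NK receptors and adaptors had 8 of 34 genes with a peak (23.5%, odds ratio 5.44, Fisher's exact test, adjusted p = 0.00204). Most of these genes, among them Klrb1b, Klri2, Klre1 and Klrd1, lie in the NK gene complex on chromosome 6. The test treats these neighbours as independent, so its p can be too small. Klrb1b, a lectin-like receptor of the NK gene complex, had 4 peaks, and the strongest, on chromosome 6 at 128836417 to 128836649 and 10.1 kb upstream, reached 19.3-fold (12.5 to 28.6). Klri2 had an intergenic peak of 7.83-fold, Klre1 a promoter peak of 6.97-fold and Klrd1 (CD94) an intergenic peak of 5.63-fold. Of the cytokine and chemokine genes, 5 of 17 had a peak (29.4%, odds ratio 7.36, Fisher's exact test, adjusted p = 0.00738): Il10, Xcl1 at 7.59-fold and 30.7 kb upstream, Csf2 at 6.44-fold at its promoter, Ifng at 6.37-fold and 29.5 kb downstream, and Ccl3 at 4.83-fold. Most of these peaks lay away from promoters: with only promoter peaks the receptor list had 1 gene (odds ratio 0.77, adjusted exact p = 1) and the cytokine list 1 gene (1.59, adjusted exact p = 1). Both calls also ended in the 727 peaks with the highest -log10 q (adjusted exact p = 0.243 and 0.244) and above the median fold (0.248 and 0.616), and the cytokine call ended within 10000 bp (0.132).

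The other effector lists did not pass the test. Cytotoxic genes had 3 of 20 with a peak (adjusted exact p = 0.172). The strongest peaks lay away from the starts: Fasl at 7.23-fold and 21.2 kb downstream, Gzmb at 6.44-fold and 21.9 kb upstream, and Gzma at 5.86-fold and 13.3 kb downstream. Gzmb also had a peak of 6.17-fold with 16 tags that overlapped its start. Apoptosis regulators had 4 of 21 (adjusted exact p = 0.0688), with promoter peaks at Bbc3, the pro-apoptotic PUMA gene (12.0-fold, 7.36 to 18.6), Bcl2l1, the BCL-XL gene (9.53-fold), and Cflar (9.28-fold), and an intronic peak at Bcl2l11, the BIM gene (5.05-fold). Cytokine receptor and JAK-STAT genes had 4 of 36 (adjusted exact p = 0.223): Il2rb, a chain of the interleukin-15 receptor, at 7.33-fold, Stat4 with 3 peaks of up to 7.17-fold, Stat3 at 5.21-fold and Pim1 at 4.02-fold. Migration and adhesion genes had 4 of 23 (adjusted exact p = 0.0832), led by Cd44 at 8.43-fold and Itga1 at 8.05-fold, with Itgb1 at 5.06-fold. Itga1 was the 1 gene with a peak among 8 markers of type 1 innate lymphoid cells (adjusted exact p = 0.536). MAP kinase pathway genes had 2 of 24 (adjusted exact p = 0.536), Map2k2 at 7.39-fold and Map3k8 at 5.63-fold.

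General cellular genes were also below the threshold. Chromatin complex genes had 5 of 29 with a peak (adjusted exact p = 0.0593), with promoter peaks at Gatad2a (7.59-fold), Smarca2 (6.60-fold), Sin3a (6.37-fold) and Eed (6.32-fold); with peaks within 10000 bp alone this list passed the threshold. Cell cycle genes had 4 of 25 (adjusted exact p = 0.0983), Ccnd3 at 9.47-fold, Cdkn1a at 6.60-fold and Cdkn1b and Cdkn2d at 6.31-fold each. Ribosomal protein genes had 5 of 39 (adjusted exact p = 0.118), all at promoters, with Rps9 at 9.46-fold, Rpl10 at 9.21-fold and Rpl7 at 7.59-fold. Glycolysis had 1 of 16, Hk2 at 7.24-fold (adjusted exact p = 0.715).

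No list of genes of other lineages passed the test. T cell markers had 2 of 21 (adjusted exact p = 0.514), Lef1 at 6.44-fold and Cd5 at 5.90-fold. B cell markers (18 genes), myeloid markers (18), erythroid and platelet markers (14), neuronal genes (18) and liver genes (16) had 0 genes with a peak, each with an adjusted p of 0.715 or 1. None of the 5 Ikaros family genes, Ikzf1 to Ikzf5, had an assigned peak (adjusted exact p = 1; the upper 95% exact bound of the share is 52.2%).

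**Figure D3:**
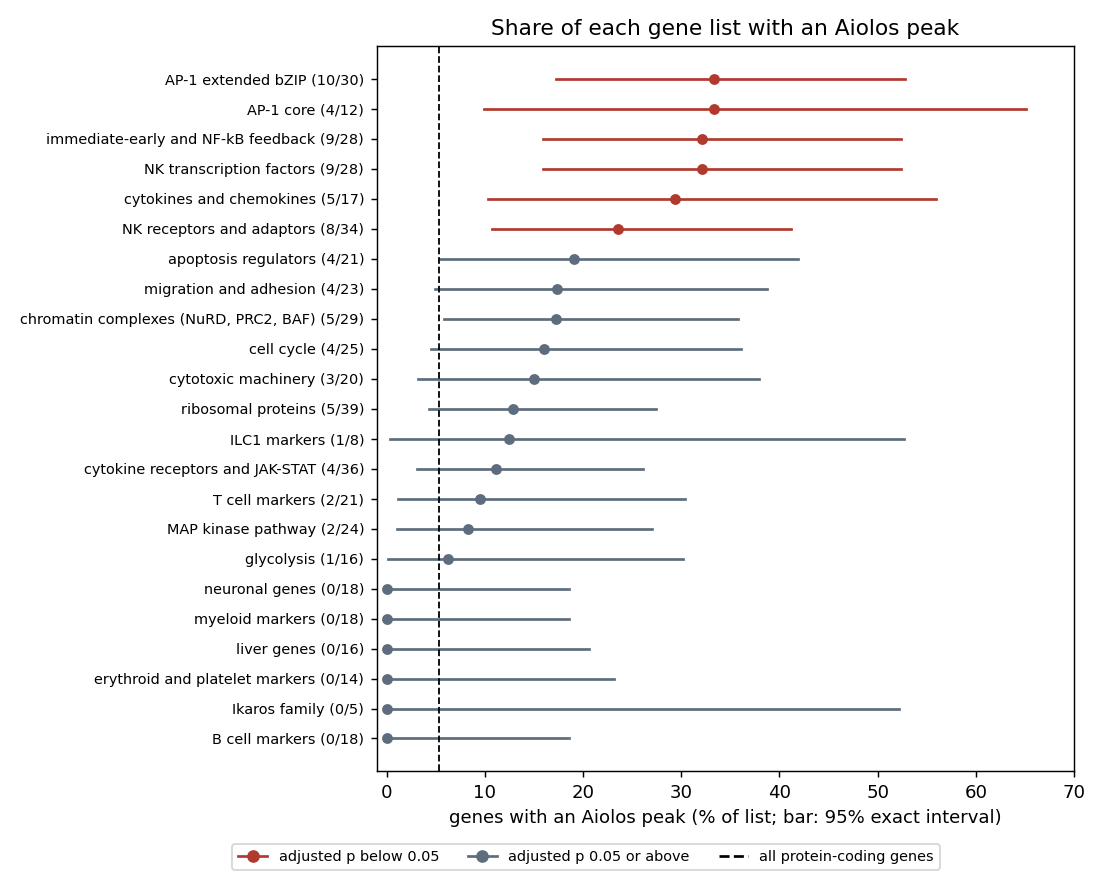
Percent of the genes of each list with an Aiolos peak (x axis), for 23 lists (y axis, genes with a peak over genes in the table). Points are shares, bars 95% exact intervals, red an adjusted p below 0.05, and the dashed line the 5.38% of all protein-coding genes; 6 lists, from NK receptors at 23.5% to the AP-1 lists at 33.3%, are red.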

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

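Matching on assignment territory, the reduced background and the use of pileup were chosen after the results had been seen; the other alternatives were planned. Keeping the peaks at or above the median -log10 q left 727, a promoter share of 69.1%, a promoter minus other difference of 0.085 log2 (permutation p = 0.147), an AP-1 core odds ratio of 6.75 and 3 enriched lists. Keeping peaks above the median fold left 687 peaks, a promoter share of 69.1%, an AP-1 core odds ratio of 7.16 and 3 enriched lists. In both sets the AP-1 core genes with a peak fell from 4 to 2, which by construction of the stricter sets leaves fewer peaks to count. The AP-1 core minus other difference in fold reversed from -0.14 to 0.54 log2 in each of them (permutation p = 0.0249 and 0.0281, 3 peaks), where the filter acts on the strength that is compared, and to 0.17 with pileup in place of fold (permutation p = 0.75); the cause of the latter was not tested. The promoter share was 59.2% with a window of 500 bp and 71.6% with 3000 bp, by construction of the window. With peaks within 10000 bp of the start the AP-1 core odds ratio was 4.18, and with promoter peaks alone it was 5.09, again with 2 genes, because the Fos and Jun peaks lie farther away; promoter peaks alone gave 3 enriched lists. All genes as background gave 13 enriched lists, since non-coding genes rarely have a peak. The bZIP, NK transcription factor and immediate-early lists passed the threshold in 10 of 10 alternatives, the NK receptor list in 7, and the AP-1 core and cytokine lists in 6 each. The promoter difference in fold kept its direction and threshold in 8 of 9 alternatives, though its size was 0.091 log2 above the median fold and 0.36 with pileup against 0.16. Depth limits the reading of single peaks: with a median of 8 tags, counting intervals of typical folds span more than a factor of 3. The alternatives of the motif test were not run, for want of a genome sequence. No paired analysis was possible because there is 1 library per group and no test between libraries.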

Other observations

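The loci, chromosomes and symbol families in this part were chosen after their values were seen, and so were the histone genes, the summit windows, the comparison with housekeeping lists and the comparison of control steps. The limit of 10000 bp was fixed before the data were examined, but its use to weigh peaks credited from far away was set after the distances had been seen; the requirement that the interval of the histone background difference exclude 0 was added after its value was seen. The T cell receptor alpha and delta locus on chromosome 14 held 4 peaks within 20 kb of its segments, of which 1 lay 1.28 kb and 1 lay 3.11 kb past the end of the last segment, the side on which the T cell receptor alpha enhancer is known to lie, at 5.63-fold and 5.39-fold. The strongest of the 4, at 54061359 to 54061721, reached 8.43-fold (4.31 to 15.3). The T cell receptor beta locus on chromosome 6 held 1 peak at 41554526 to 41554966, of 13.9-fold (8.45 to 21.9), which the nearest-gene annotation credits to Prss2. The T cell receptor gamma locus and the 3 immunoglobulin loci held 0 peaks, and the difference between the loci was not tested. On chromosome 6, the 1.68 Mb from Klrb1 to Klra1, the NK gene complex, held 10 peaks, of which 1 was at a promoter.

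The strongest peak of the list lay on chromosome 7 at 106236535 to 106237148, in intergenic sequence 21.2 kb from Gm4070, at 25.3-fold (17.4 to 35.5). Tex14 had the most peaks of any gene, 5, and Per1 and Dad1 had 4 each, as did Fosb and Klrb1b. On the X chromosome 13 of 966 protein-coding genes had a peak (1.35%), against 5.64% on the autosomes, which ranged from 3.31% to 8.19% (odds ratio 0.23, Fisher's exact test, unadjusted p = 3.2e-11). Without olfactory receptor, vomeronasal receptor and Gm genes it was 13 of 832 (1.56%) against 6.35% (Fisher's exact test, unadjusted p = 7.29e-11). Among 680 symbol families with at least 5 genes, Gm (4 of 1329), Olfr (2 of 1110) and Vmn (0 of 355) had fewer genes with a peak than the rest, and the family starting with H (25 of 145, Fisher's exact test, adjusted p = 3.8e-05) had more.

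AP-1, immediate-early and NK cell genes carried peaks more often than other genes, and no biological explanation was tested, since the design has no group without Aiolos. Longer genes collecting more nearest-gene assignments is argued against. Against random lists matched on assignment territory, 5 of 5 lists kept an adjusted p below 0.05 (highest adjusted p 0.0222). This territory is bounded by protein-coding neighbours only, so it approximates the sequence from which a gene can be assigned a peak. Peaks credited from far away are argued against as the only source for the immediate-early and NK transcription factor lists. With peaks whose edge lay within 10000 bp of the start these lists kept the threshold (Fisher's exact test, adjusted p = 6.08e-05 and 0.0159). The NK receptor list also kept it (Fisher's exact test, adjusted p = 0.0232), with 6 of 34 genes. Among them was Klrb1c, whose peak edge lay 9898 bp from its start. A limit measured from the peak centre was not tested, so far peaks stay open for this list. The lists were grouped after this outcome was known, so their number adds no support. The receptor genes are mostly neighbours in the NK gene complex, and with promoter peaks alone 1 of 34 was left. Far peaks also stay open for the AP-1 core and cytokine lists, whose odds ratios of 4.18 and 4.48 within 10000 bp rest on 2 and 3 genes. Open promoters of any active gene, cut without regard to Aiolos, may contribute to the promoter part, which the pooled test does not decide. There 17 of 119 genes of the 5 lists had a peak against 12 of 109 ribosomal protein, glycolysis, cell cycle and chromatin complex genes (odds ratio 1.35, Fisher's exact p = 0.552). The pool mixes 7 of 28 immediate-early, 6 of 28 NK transcription factor, 2 of 12 AP-1 core, 1 of 34 NK receptor and 1 of 17 cytokine genes. Against other protein-coding genes the immediate-early and NK transcription factor lists kept the threshold (Fisher's exact test, adjusted p = 0.00147 and 0.00604). Over all genes a background on whole steps of 0.586 tags, 1 form of local control signal, was seen at 29.9% of promoter peaks against 23.1% of others (odds ratio 1.42, Fisher's exact p = 0.00707). Control tags spread over wider windows are not counted there. With any peak the pooled counts were 35 of 119 against 15 of 109, of which 18 and 3 genes had peaks away from the promoter alone. An excess there was built in, as the 5 lists had been picked for their peaks, so no p is given for it.

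Histone genes carried peaks in 21 of 74 cases (28.4%, 95% exact interval 18.5 to 40.1) against 5.30% of other protein-coding genes (odds ratio 7.08, Fisher's exact test, unadjusted p = 1.83e-10), 17 of them in the clusters on chromosome 13, so the genes are not independent. H3c11 reached 11.0-fold (6.07 to 18.5) and H3c1 10.1-fold (5.93 to 16.2). Reads shared between near-identical coding sequences may contribute: 58.3% of 24 promoter summits lay outside every histone gene (14 summits, exact interval 36.6 to 77.9), which leaves it open. A higher control background at these loci also stays open, since the median background was 0.261 tags against 0.315 at other promoter peaks, a difference of -0.0546 (permutation p = 0.668) whose bootstrap interval, -0.121 to 0.222, spans 0; the difference met the bound set beforehand, a median at or below that of other promoter peaks, but by less than its spread. No biological explanation was tested.

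Promoter summits lay upstream or downstream of the start with few in the 100 bp upstream of it. Of 880 genes with a promoter peak, 15 had summits on both sides. With 910 promoter peaks in all, most of these genes had a single summit, which cannot lie on both sides. The count therefore does not tell whether the clusters sit at different genes. Misplaced starts stay open: among 432 peaks whose start lies within 50 bp of an end of the same gene in the gene table, the gap held 11.6% of the windowed summits (upper exact bound 16.2, equal density 28.6), but both annotations can share an error. Chance placement of the summits of weak peaks is argued against, since with these left out, among 301 peaks with more than 10 tags, the share was 7.19% (upper bound 12.2). Divergent neighbours with an end in the gene table are argued against as the only source of the upstream cluster. Among 563 peaks with no other such end within 1000 bp, the gap held 21.2% of the summits in the gap and the upstream window (upper bound 27.7, equal density 40). Divergent transcripts that start elsewhere stay open, as only 432 of the 910 promoter peaks had a start within 50 bp of an end of their gene. The windows were picked from these same summits, so a share below equal density was in part built in. A candidate explanation is cutting around the nucleosomes that flank the start, or loss of peaks in the gap to signal of the library without antibody; positions without a called peak are not in the list, so neither was tested.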
